A study of Mus musculus with 19 samples.

How the data were processed

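Faecal DNA of 19 mice was sequenced over the V4 region of the bacterial 16S rRNA gene on an Illumina NovaSeq, per the labels. Relative abundances were deposited by the authors as a fraction of each sample's sequences for 10 bacterial classes and a remainder, and were turned into percent here. The Shannon index was deposited as a score per sample, as were the coordinates on 2 axes of each of 2 principal coordinates analyses of weighted UniFrac distances. The submitters' processing notes name R 2.15.3 and the genome build mm9, without saying for which step. The tools for merging, clustering and classifying the reads, any rarefaction, the base of the Shannon logarithm and the variance explained by each axis are not given in the sources used here. Class names are those of the table, and the sources used here do not say what "unidentified" marks in some of them. No read counts or depths are given in the sources used here, so depth is taken as unknown, and no interval or detection floor is given. All samples summed to 100%, 0 values were zero, and 0 pairs of samples were identical.

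Samples were grouped by their titles into PBS, AZ1, DSS with PBS (replicates 2 to 5) and DSS with AZ1. The treatment labels of the AZ1 mice carry running numbers, and those of the DSS mice a different spelling; the titles were followed. The ordination named for DSS holds the samples titled without DSS, and the other the samples titled with DSS; rows were taken by sample name. The 2 ordinations are separate, so positions were compared only within each.

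The comparisons were AZ1 against PBS without DSS, AZ1 against PBS with DSS, DSS against no DSS under PBS and under AZ1, and the interaction of AZ1 and DSS. Differences of group means were tested with two-sided exact permutation tests over all splits of the samples, with Benjamini-Hochberg adjustment over the 11 entries of the class table within a comparison and a threshold of 0.05; the remainder was adjusted for but not counted as a class. The smallest exact p is 0.00794 for 5 against 5 and for 4 against 5 mice, and an entry at that value is adjusted to 0.0873 where no other entry has a small p. Shannon differences were called on the exact p, with the value adjusted over 4 comparisons beside it. Communities were compared by PERMANOVA, as R2 with an exact p, on Bray-Curtis dissimilarity of the class table and on Euclidean distance over the 2 UniFrac axes. Interactions were tested by permuting the residuals of the additive model 100000 times. Summed taxon lists and the log2 Firmicutes to Bacteroidetes ratio made 7 tests per comparison, adjusted together. The list of diet or host derived 16S (plant chloroplasts, mitochondria) had 0 members among the classes. By a rule set before the data were examined, every class of the table is named in each comparison, since it held no more than the limit of the rule; the tests, lists and other settings were set then too.

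The alternatives were log2 values with a pseudocount of 0.01 or 0.1 percent, centred log-ratios, rank-sum tests with Hodges-Lehmann shifts, limma on log2 values over the 4 groups, a minimum mean of 0.1%, shares of the listed classes alone, single or rescaled UniFrac axes, ranks of the Shannon index, leaving out each mouse, and the replicate number as a block. Whether same-numbered mice deviate together was checked by correlating their deviations from the group means in centred log-ratios. Only for DSS against no DSS under AZ1 were all 5 correlations over 0.1, from 0.150 to 0.735, with 3 of the 5 mice closest to their own number. This pairing is a hint from the data, and the labels do not state it. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. The tests were run on simulated data in 200 simulations per setting, with 2 of 11 entries changed. Of these changes, 13.2% of 2-fold and 84.8% of 8-fold ones were called for DSS under AZ1. Entries were drawn independently on a log scale, with the spread of the second-named group in both groups. They were not rescaled to a fixed sum, and the remainder could be among those changed. These rates therefore need not hold for the real shares. With no simulated effect, PERMANOVA gave p under 0.05 in 6.5% and the interaction test in 7% of simulations. These runs used random numbers not shaped like the class table, with fewer resamples for the interaction test. Shares from 200 runs are also imprecise, so they give no error rate for the tests on the real data.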

Results

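The data were bacterial 16S rRNA gene profiles of faeces from 19 wild-type C57BL/6 mice, an inbred laboratory strain, aged 8 weeks. The mice fell into 4 groups: PBS, the vehicle (n = 5); AZ1, reported in the literature as a small-molecule inhibitor of the deubiquitinases USP25 and USP28 (n = 5); DSS with PBS (n = 4); and DSS with AZ1 (n = 5). DSS stands for dextran sulfate sodium, a polymer that damages the colonic lining and is widely used to induce colitis in mice, and was given at 2.5%. For each sample the values were the relative abundance of 10 bacterial classes and of a remainder, a Shannon index of diversity and a position on 2 axes of a weighted UniFrac ordination. Sequencing depth per sample is unknown, since the values are shares and scores, and no counting error is attached to them. The labels do not say whether the samples of a group came from separate cages. Each exact p is the share of splits of these samples that differ at least as much, and takes the samples as independent. If the groups were caged apart, a cage difference could not be told apart from AZ1 or DSS. The ordination holding the mice without DSS is named for DSS and the other one the opposite way; samples were placed by their own names, and every direction given for DSS rests on those names.

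Bacteroidia, the class that holds many polysaccharide-degrading gut anaerobes, was the most abundant in each group, with a mean of 46.2% ± 8.11 (SD, n = 5) under PBS. Verrucomicrobiae, the class of the mucin-degrading genus Akkermansia, had a mean of 16.0% ± 4.82 (SD, n = 5) under PBS. Clostridia, which hold many butyrate producers, had 11.3% ± 3.22, and Bacilli, the class of the lactobacilli, had 13.3% ± 6.93 (SD, n = 5 each). The remainder outside the 10 classes was between 0.0286% and 0.477% of a sample.

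**Figure D1:**
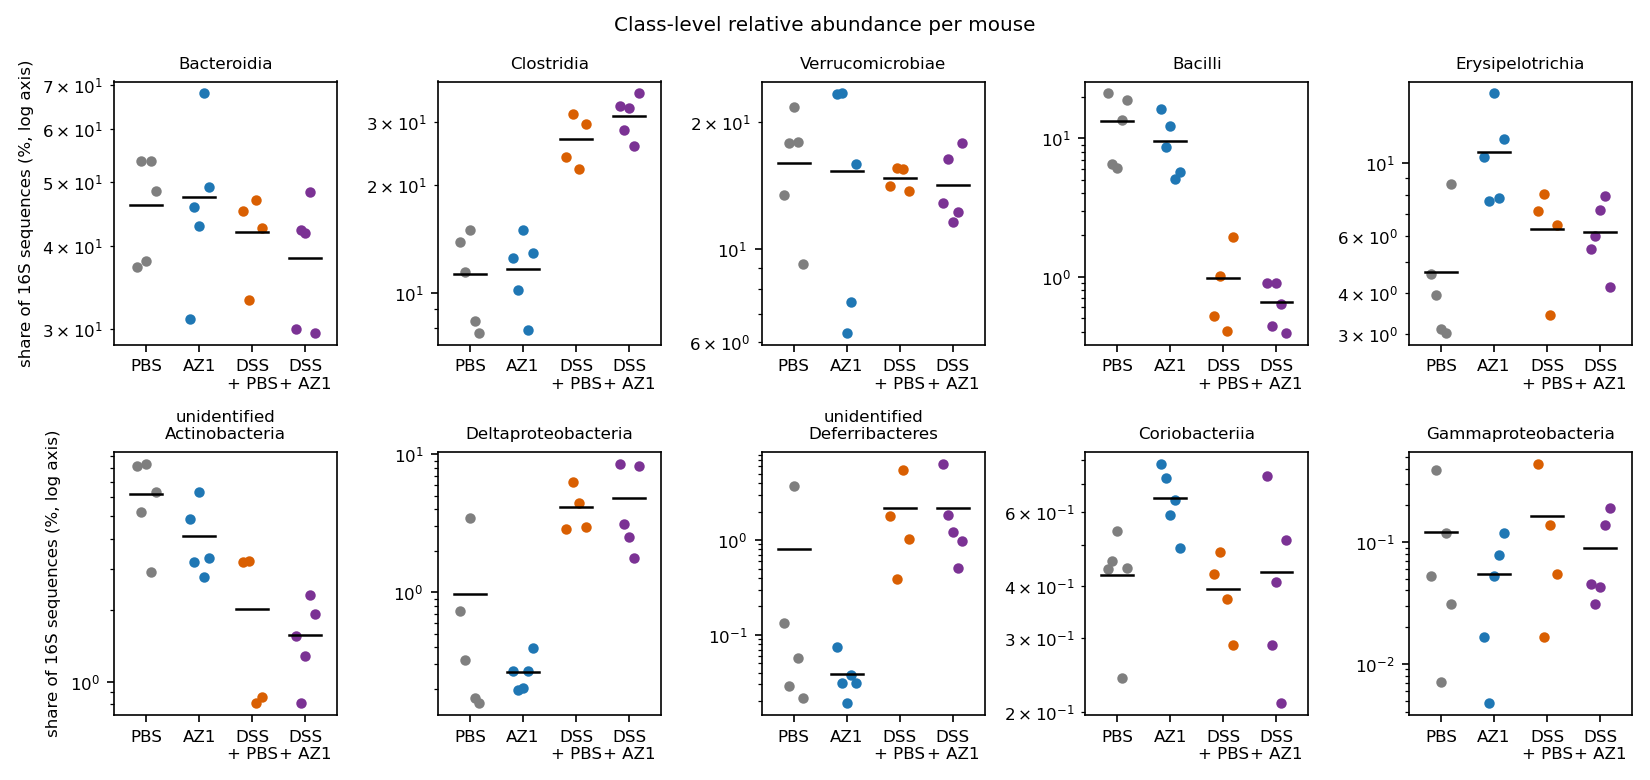
Relative abundance of the 10 bacterial classes, in percent of 16S sequences on a log axis whose range differs between panels, with a dot per mouse and a black line at the group mean (n = 5, 5, 4 and 5 from left to right). Clostridia in the mice with DSS all lie above those in the mice without, and Bacilli all lie below.

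The first comparison asked how AZ1 alone relates to the faecal community, in mice that had no DSS. Erysipelotrichia, a Firmicutes class common in the rodent gut, had a mean of 10.8% ± 3.54 with AZ1 and 4.66% ± 2.30 with PBS (SD, n = 5 each), a ratio of 2.32. Coriobacteriia, a class of Actinobacteria with several bile acid and steroid converters, had 0.648% ± 0.114 with AZ1 and 0.424% ± 0.111 with PBS (SD, n = 5 each), a ratio of 1.53. Neither difference passed the test after adjustment (exact p = 0.0238 and 0.0159, both adjusted to 0.131). The exact permutation test called 0 of the 10 classes, and 2 had an unadjusted p under 0.05.

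Bacteroidia had 47.3% ± 13.4 with AZ1, Clostridia 11.7% ± 2.73 and Verrucomicrobiae 15.3% ± 8.27, each within 1 SD of the PBS mean. Bacilli had 9.59% ± 4.72 with AZ1, a difference of -3.67 percentage points from PBS (exact p = 0.341). The unidentified Actinobacteria, a label that the sources used here do not explain, had 4.10% ± 1.49 with AZ1 and 6.18% ± 2.25 with PBS (exact p = 0.143). Deltaproteobacteria, which include the sulfate-reducing gut bacteria, had 0.266% ± 0.0794 with AZ1 and 0.970% ± 1.41 with PBS (exact p = 0.333). The unidentified Deferribacteres, a phylum found in the mouse gut mainly as the mucus dweller Mucispirillum, had 0.0386% ± 0.0209 with AZ1 and 0.798% ± 1.65 with PBS (exact p = 0.270). PBS replicate 3 alone held 3.46% and 3.75% of these last 2 groups. Gammaproteobacteria, the class of Escherichia, had 0.0544% ± 0.0466 with AZ1 and 0.120% ± 0.157 with PBS (exact p = 0.540).

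Of the taxon lists fixed before the data were examined, none passed the test for AZ1 without DSS. The 3 Firmicutes classes summed to 32.1% ± 9.27 with AZ1 and 29.2% ± 7.81 with PBS, and 0 of them passed either adjusted over the list alone or over all classes. Of the 2 Actinobacteria classes, Coriobacteriia passed adjusted over the list alone (exact p adjusted to 0.0317) and 0 passed over all classes. In the Proteobacteria list and the list of facultative or microaerophilic classes (Bacilli and Gammaproteobacteria), 0 of 2 members passed on either adjustment. The Shannon index was 4.93 ± 0.241 with AZ1 and 4.95 ± 0.127 with PBS, a difference of -0.0175 ± 0.122 (SE, exact p = 0.865). The split into AZ1 and PBS accounted for 11.8% of the variation in Bray-Curtis dissimilarity (exact p = 0.381) and 1.89% of that on the UniFrac axes (exact p = 0.857). Each p is the share of all splits of these mice with an R2 at least as large. With limma on log2 values, 1 class was called, Erysipelotrichia (log2 difference 1.27, limma adjusted p = 0.0110). In data simulated for this comparison, 6.25% of entries changed 2-fold were called, so in that setting changes of that size mostly went undetected. The simulated entries were independent and had no fixed sum, so the rate need not hold for the real shares.

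The second comparison set AZ1 against PBS in the mice that had DSS. Clostridia had a mean of 31.3% ± 4.12 with AZ1 (SD, n = 5) and 26.8% ± 4.49 with PBS (SD, n = 4), with an exact p of 0.159. Bacteroidia had 38.4% ± 8.28 and 42.0% ± 6.14, and Verrucomicrobiae 14.2% ± 2.74 and 14.7% ± 0.936. Erysipelotrichia had 6.15% ± 1.48 with AZ1 and 6.28% ± 2.00 with PBS (exact p = 0.889). The exact permutation test called 0 of 10 classes after adjustment and 0 at an unadjusted p under 0.05, and limma on log2 values called 0.

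Deltaproteobacteria had 4.84% ± 3.28 with AZ1 and 4.16% ± 1.62 with PBS, and the unidentified Deferribacteres 2.19% ± 2.41 and 2.19% ± 2.32. Bacilli had 0.653% ± 0.243 and 0.970% ± 0.698, and the unidentified Actinobacteria 1.58% ± 0.584 and 2.03% ± 1.37. Coriobacteriia had 0.431% ± 0.206 and 0.392% ± 0.0824, and Gammaproteobacteria 0.0892% ± 0.0702 and 0.162% ± 0.191. None of the taxon lists passed the test, and 0 members of any list did so adjusted over the list alone. The Shannon index was 5.35 ± 0.105 with AZ1 and 5.13 ± 0.200 with PBS, a difference of 0.218 ± 0.110 (SE, exact p = 0.0714, adjusted to 0.143 over 4 comparisons). With each mouse left out in turn, this difference ran from 0.163 to 0.313. Only the highest, without DSS with PBS replicate 5, had an exact p under 0.05 (0.0179, unadjusted). The split into AZ1 and PBS accounted for 9.88% of the Bray-Curtis variation (exact p = 0.444) and 9.04% of that on the UniFrac axes (exact p = 0.460). Each p is the share of all splits of these mice with an R2 at least as large. In simulated data, 10.2% of entries changed 2-fold and 29.5% of those changed 8-fold were called here.

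**Figure D2:**
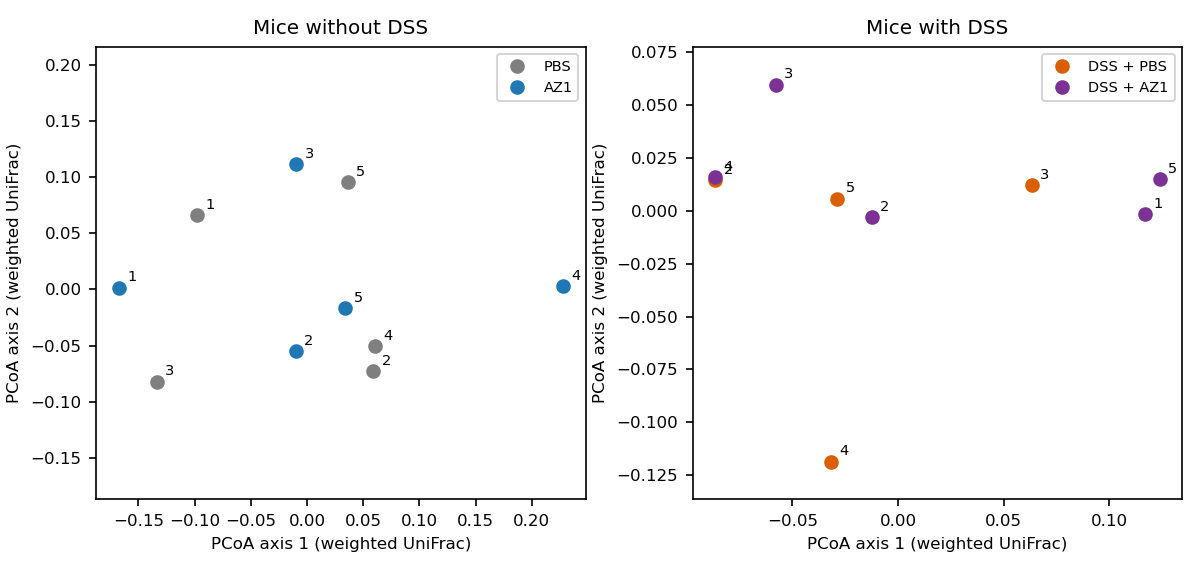
Positions of the mice on the 2 deposited weighted UniFrac axes (unitless), without DSS at left and with DSS at right, each an ordination of its own, with a dot per mouse and its replicate number beside it. AZ1 and PBS mice overlap in both panels, and DSS with PBS replicate 4 lies at -0.119 on axis 2.

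The third comparison asked how DSS relates to the community under PBS. Clostridia had a mean of 26.8% ± 4.49 with DSS (SD, n = 4) and 11.3% ± 3.22 without (SD, n = 5), a ratio of 2.38. Bacilli were 13.7-fold lower in mean, at 0.970% ± 0.698 with DSS and 13.3% ± 6.93 without. Every mouse with DSS lay above every mouse without for Clostridia and below for Bacilli. After adjustment over the table neither passed, since the exact p of 0.00794 for Clostridia, the smallest that 4 against 5 mice can give, and of 0.0238 for Bacilli both became 0.0873. The exact permutation test called 0 of 10 classes, with 4 at an unadjusted p under 0.05.

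The unidentified Actinobacteria had 2.03% ± 1.37 with DSS and 6.18% ± 2.25 without (exact p = 0.0317, adjusted 0.0873), and Deltaproteobacteria had 4.16% ± 1.62 and 0.970% ± 1.41 (exact p = 0.0317, adjusted 0.0873). The unidentified Deferribacteres had 2.19% ± 2.32 and 0.798% ± 1.65 (exact p = 0.373), a difference of 1.39 points that was 0.270 without DSS with PBS replicate 4 and 2.13 without PBS replicate 3. Bacteroidia differed by -4.18 percentage points, Verrucomicrobiae by -1.33, Erysipelotrichia by 1.62, Coriobacteriia by -0.0317 and Gammaproteobacteria by 0.0420, with exact p-values from 0.302 to 0.635. Among the 3 Firmicutes classes, 2 passed adjusted over the list alone, Clostridia (higher) and Bacilli (lower), and 0 over all classes. Bacilli also passed in the facultative list adjusted over the list alone (exact p adjusted to 0.0476), and 0 of its 2 members did over all classes. In the Proteobacteria and Actinobacteria lists, 0 of 2 members passed on either adjustment. The summed Firmicutes were 34.1% ± 6.59 and 29.2% ± 7.81 (exact p = 0.341). The Proteobacteria and Actinobacteria sums each had an exact p of 0.0317 and the facultative sum 0.0238, all adjusted to 0.0741 over the lists.

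The Shannon index was 5.13 ± 0.200 with DSS and 4.95 ± 0.127 without, a difference of 0.186 ± 0.115 (SE, exact p = 0.119) that was 0.0917 without DSS with PBS replicate 5. The mice with and without DSS separated as whole communities. The split by DSS accounted for 54.4% of the Bray-Curtis variation (exact p = 0.00794, adjusted to 0.0159 over 4 comparisons). Taken as same-numbered pairs, the exact p was 0.125, the smallest 4 pairs can give, with a partial R2 of 0.821. The count of 0 depended on the scale and on the test: the exact test called 2 classes on log2 values (Clostridia higher, Bacilli lower) and 3 on centred log-ratios (also the unidentified Actinobacteria, lower). Limma, another test on the same log2 values, called 5 (those 3 with Deltaproteobacteria and the unidentified Deferribacteres, higher). In simulated data, 11.5% of entries changed 2-fold and 52.8% of those changed 8-fold were called in this comparison.

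The fourth comparison asked how DSS relates to the community in mice given AZ1. Clostridia rose from 11.7% ± 2.73 to 31.3% ± 4.12 (SD, n = 5 each), a ratio of 2.67. Deltaproteobacteria rose 18.2-fold, from 0.266% ± 0.0794 to 4.84% ± 3.28, and the unidentified Deferribacteres rose 56.7-fold, from 0.0386% ± 0.0209 to 2.19% ± 2.41. Bacilli fell from 9.59% ± 4.72 to 0.653% ± 0.243 and were 14.7-fold lower, and the unidentified Actinobacteria fell from 4.10% ± 1.49 to 1.58% ± 0.584. Erysipelotrichia fell from 10.8% ± 3.54 to 6.15% ± 1.48 and were 1.76-fold lower.

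These 6 of 10 classes, 3 higher and 3 lower, were called by the exact permutation test, and the same number had an unadjusted p under 0.05. For 5 of them every mouse with DSS lay on one side of every mouse without (exact p = 0.00794, the smallest 5 against 5 mice can give, adjusted 0.0175); for Erysipelotrichia the exact p was 0.0238, adjusted 0.0437. Bacteroidia differed by -8.94 percentage points (exact p = 0.214), Verrucomicrobiae by -1.14 (exact p = 0.754), Coriobacteriia by -0.217 (exact p = 0.0952, but called as lower on centred log-ratios with an adjusted exact p of 0.0125) and Gammaproteobacteria by 0.0348 (exact p = 0.381). All 3 Firmicutes classes passed both adjusted over the list alone and over all classes, Clostridia upward and the other two downward, while their sum was 38.1% ± 3.20 with DSS and 32.1% ± 9.27 without (exact p = 0.206). The log2 ratio of Firmicutes to Bacteroidetes was 0.01 ± 0.42 with DSS and -0.56 ± 0.80 without (exact p = 0.183). The Proteobacteria sum rose from 0.320% to 4.93%, the facultative sum fell from 9.64% to 0.742% and the Actinobacteria sum fell from 4.75% to 2.01% (exact p = 0.00794 each, adjusted to 0.0185 over the lists). In each of these 3 lists 1 of 2 members was called, on either adjustment, namely Deltaproteobacteria, Bacilli and the unidentified Actinobacteria.

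The Shannon index rose with DSS under AZ1 from 4.93 ± 0.241 to 5.35 ± 0.105, a difference of 0.422 ± 0.118 (SE, exact p = 0.00794, adjusted 0.0317). The split by DSS accounted for 57.5% of the Bray-Curtis variation (exact p = 0.00794, adjusted 0.0159). With same-numbered mice taken as pairs, the exact p of both became 0.0625, the smallest 5 pairs can give, with a partial R2 of 0.893 for the Bray-Curtis test. Limma with the replicate number as a block, a pairing the labels do not state, also called Coriobacteriia lower and Gammaproteobacteria higher (limma adjusted p = 0.0471 and 0.0372). The Gammaproteobacteria call came in no other setting. Limma over the 4 groups gave the same log2 difference of 0.729 (limma adjusted p = 0.448), in a class with means of only 0.0892% with DSS and 0.0544% without. The count fell to 3 without AZ1 replicate 3 or replicate 5 (Clostridia, Bacilli and the unidentified Actinobacteria), and the Erysipelotrichia call ended without any one of the mice given DSS and AZ1, with differences from -5.11 to -4.16 points and adjusted exact p-values from 0.0582 to 0.102. It ended too without AZ1 replicate 3 (-3.29 points, adjusted exact p = 0.0582) or 5 (-4.40 points, adjusted exact p = 0.0524). It also ended in the rank-sum test (shift of -3.91 points, adjusted exact p = 0.0582), where the other settings with all mice gave 0.0125 to 0.0460. Without DSS with AZ1 replicate 1, which held 6.42% Deferribacteres, the Deferribacteres difference was 1.10 points (adjusted exact p = 0.0291), against 2.152 with all mice (adjusted exact p = 0.0175). The Deltaproteobacteria and Deferribacteres calls ended without AZ1 replicate 2, 3, 4 or 5 (adjusted exact p from 0.0524 to 0.0582), and the Proteobacteria sum's call without any one of the 5 AZ1 mice (adjusted exact p = 0.0556), with the Deltaproteobacteria difference between 4.56 and 4.61 points and that of Deferribacteres between 2.147 and 2.152.

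**Figure D3:**
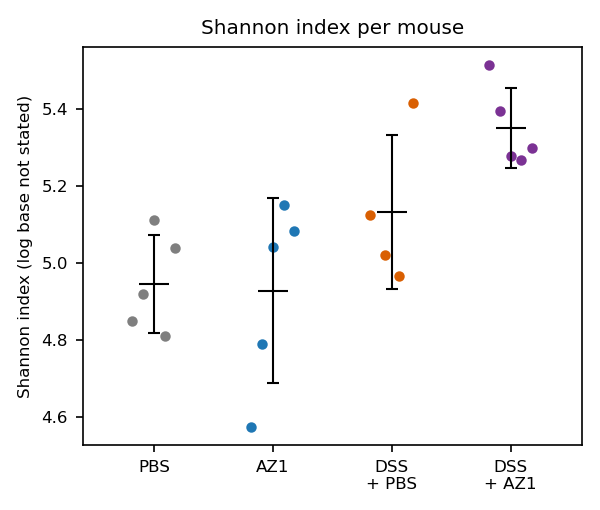
Shannon index of each mouse (unitless, base of the logarithm not stated) in the 4 groups, with a dot per mouse and bars for the mean ± SD (n = 5, 5, 4 and 5). Mice given DSS and AZ1 have a mean of 5.35 and mice given AZ1 alone a mean of 4.93.

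Whether the AZ1 difference depended on DSS was tested directly over all 19 mice. Erysipelotrichia were 6.16 percentage points higher with AZ1 than with PBS in mice without DSS and differed by -0.123 in mice with DSS, an interaction of -6.28 points (permutation p = 0.00847, adjusted 0.0932). No class passed after adjustment, and Erysipelotrichia was the 1 class with an unadjusted p under 0.05. The interaction was -4.76 points for Bacteroidia, 3.99 for Clostridia, 3.35 for Bacilli, 1.64 for the unidentified Actinobacteria and 1.38 for Deltaproteobacteria, with permutation p-values from 0.221 to 0.576. It was 0.759 points for the unidentified Deferribacteres, 0.192 for Verrucomicrobiae, -0.185 for Coriobacteriia and -0.00716 for Gammaproteobacteria (permutation p from 0.145 to 0.966). For the Shannon index it was 0.236 (permutation p = 0.139). The Erysipelotrichia interaction passed the adjusted test without PBS replicate 5 (-7.27, permutation p adjusted to 0.0195), AZ1 replicate 2 (-7.06, 0.0456) or DSS with PBS replicate 4 (-7.22, 0.0467), and the Shannon interaction had an unadjusted permutation p of 0.0317 without DSS with PBS replicate 5 (0.330).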

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

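The tests of explanations in this part were all chosen after the class values had been seen, and the counts over other splits of the mice after the calls were known. In 56 sets of values from a group of mice, 5 held a mouse far from the others by Dixon's criterion, where chance flags about 1 in 20 groups, or 2.8 here. Erysipelotrichia in PBS replicate 5 were 8.60%, against 3.03% to 4.58% in the other PBS mice. In PBS replicate 3, Deltaproteobacteria were 3.46% (others 0.157% to 0.735%) and the unidentified Deferribacteres 3.75% (others 0.0215% to 0.134%). The unidentified Deferribacteres were 6.42% in DSS with AZ1 replicate 1 (others 0.503% to 1.83%). On UniFrac axis 2, DSS with PBS replicate 4 lay at -0.119 (others 0.00575 to 0.0144). The AZ1 difference in Erysipelotrichia differed between mice with and without DSS by -6.28 points, at an unadjusted permutation p of 0.00847 that became 0.0932 after adjustment.

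With the mice taken as unpaired, 1 of 100 splits gave as many called classes as the 6 for DSS under AZ1. It was the real split, and the highest of the others gave 0. These splits are among those of the exact test that made the calls. They restate its p-values and do not exclude chance on their own. Taken as same-numbered pairs, only 16 splits part all 5 pairs, too few for a share under 0.05; the real one gave 6 and the highest other 0. The other counts were all 0 in the real grouping, which 100 of 100 splits match whatever the data, so there the splits decide nothing about chance. The highest of the other splits gave 0 classes for AZ1 without DSS, 0 for AZ1 with DSS, 2 for DSS under PBS and 3 for the interaction.

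The first pattern is the shift of classes with DSS, with Clostridia higher and Bacilli lower in both arms. Shares sum to 100%, so a loss of Bacilli alone could raise the rest. With Bacilli left out the Clostridia ratio was 2.09 under PBS and 2.41 under AZ1 (exact p = 0.00794 each). This argues against a loss of Bacilli alone as the whole cause. Bacilli averaged only 13.3% under PBS and 9.59% under AZ1 without DSS, so their removal could lower these ratios only slightly. Falls of several classes together were not tested. Sample names exchanged between the ordinations and the class table are argued against by the agreement of distances between same-named mice in both (smaller Mantel r = 0.887, permutation p = 2e-05); an exchange of names in all tables at once was not testable and would turn every DSS direction. Separate housing, sampling or sequencing of the mice with and without DSS cannot be told apart from DSS, since 0 samples carry a batch label. A biological effect of DSS also stays open as a hypothesis.

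The second pattern is the higher Erysipelotrichia with AZ1 in mice without DSS, which did not pass after adjustment. A loss of Bacilli as the whole cause is argued against by a ratio of 2.19 with Bacilli left out (exact p = 0.0238). The small share of Bacilli bounds that test here too, and falls of several classes together were not tested. AZ1 replicate 3 as the sole carrier is argued against by a ratio of 2.03 without it (exact p = 0.0317). A cage difference stays open: the other classes gave no separation of AZ1 from PBS (exact p = 0.770), but this does not exclude one. An effect of AZ1 is a candidate explanation that these data do not establish.

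The third pattern is PBS replicate 3, which held Deltaproteobacteria and Deferribacteres at levels seen in mice with DSS. A library from a mouse with DSS is argued against by its Bacilli of 6.10%, above the highest of the 9 mice with DSS at 1.94% (SD 0.490). A mixed sample stays open: its Clostridia were the highest among PBS mice (15.0%, others 7.74% to 13.9%) and its Bacilli the lowest (others 6.50% to 21.1%), which goes with one, while its Actinobacteria of 8.33%, the second test of that explanation, go against it. Supplying its Deferribacteres would take 58.0% of DSS with AZ1 replicate 1 and allow at most 4.32% (SD 0.924), or 67.0% of DSS with PBS replicate 4 and at most 3.23%. These bounds assume that the rest of the library was like the other 4 PBS mice and cover only the 9 sequenced mice with DSS; a first test, on Clostridia against the lowest with DSS (22.1%), was set aside because it assumed a nearly pure foreign library, and no biological explanation was tested.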

How the results depend on the processing

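The alternatives in this part were planned before the data were examined, and the sign changes below are all in differences that passed no test. Among the values that answer a comparison, 218 were tallied as kept, 5 changed sign, 2 came to pass, 3 ceased to pass and 11 counts moved by over 1.5 times. Kept meant the same direction and side of the threshold for differences, and the same side alone for R2, which has no direction. For counts of called classes it meant a change of at most 1.5 times, so a move from 6 to 4 or 8 was tallied as kept. Among single classes and lists 1004 kept direction and side, 79 changed sign, 24 came to pass and 21 ceased to. Unless named, the cause was not tested. Per-class interaction estimates had been left out of this tally after a first look and were put back.

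By rank-sum shifts, the Shannon difference for AZ1 without DSS was 0.00371, Bacteroidia there -2.56, and with DSS Deltaproteobacteria -0.113 and Deferribacteres 0.0859. For AZ1 with DSS, log2 values with 0.01 added gave Erysipelotrichia 0.00564, Deferribacteres 0.0654 and the Proteobacteria sum -0.0229 (the first 2 also with limma), log2 values with 0.1 added gave 0.00483 and 0.0483, and centred log-ratios gave Verrucomicrobiae 0.0138, Erysipelotrichia 0.0915 and Deferribacteres 0.154. Verrucomicrobiae with DSS under AZ1 were 0.0731 on log2 values, with limma and with limma's block, and 0.0711 with 0.1 added. The interaction was 0.251 for Gammaproteobacteria on log2 values and with limma, and 0.365 on centred log-ratios, where Bacilli gave -0.0308. Limma called 1 class for AZ1 without DSS, Erysipelotrichia, and 0 with the replicate number as a block, at the same log2 difference of 1.27 (limma adjusted p = 0.0907). For DSS under PBS, 2 classes were called on log2 values with either pseudocount, 3 on centred log-ratios, 5 by limma and 4 by limma with the block.

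With the replicate number as a block, limma gave Erysipelotrichia 0.0395, Deltaproteobacteria -0.267 and Coriobacteriia -0.192 for AZ1 with DSS. In the block tests the Shannon difference for DSS under AZ1 was 0.422 and the partial R2 0.893 (exact p = 0.0625 each), and under PBS the partial R2 was 0.821 (exact p = 0.125); 5 and 4 pairs cannot give a smaller p, so the loss is by construction. For DSS under AZ1, centred log-ratios called 7 classes, adding Coriobacteriia (-1.21, adjusted exact p = 0.0125). Limma with the block called 8 classes for DSS under AZ1, adding Coriobacteriia (lower) and Gammaproteobacteria (higher, called in no other setting). Correlations of same-numbered mice ran from -0.659 to 0.465 for AZ1 without DSS and -0.665 to 0.379 with DSS. They ran from -0.00747 to 0.639 for DSS under PBS. So few pairs neither show nor exclude a pairing there, and the labels do not state one. The block changed no other Shannon or community call.

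The rank-sum test ended the Erysipelotrichia call for DSS under AZ1 (-3.91, adjusted exact p = 0.0582), leaving 5 classes.

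Leaving out each mouse in turn moved 54 of the 69 values that passed no test, and 1 of the 12 that did, by over 1.5 times or turned their sign. The called one was the Deferribacteres difference for DSS under AZ1, at 1.10 points without DSS with AZ1 replicate 1. R2 for AZ1 without DSS ran from 0.0879 to 0.185 on Bray-Curtis and 8.11e-06 to 0.105 on the UniFrac axes, and with DSS from 0.0429 to 0.227 and 0.0410 to 0.190, none past the threshold. Ranges follow for the other values that moved so, for the counts and for the Shannon difference for AZ1 with DSS, which moved by less but passed without 1 mouse. For AZ1 without DSS they were -0.0734 to 0.0711 for Shannon, -3.98 to 5.24 for Bacteroidia, -0.462 to 1.38 for Clostridia, -2.75 to 1.53 for Verrucomicrobiae, -0.0941 to 0.00191 for Gammaproteobacteria, -5.46 to -1.70 for Bacilli, -0.907 to -0.0813 for Deltaproteobacteria, -0.953 to -0.0216 for Deferribacteres, 0.0786 to 5.76 for the Firmicutes sum, -0.995 to -0.175 for the Proteobacteria sum, -5.55 to -1.79 for the facultative sum and -0.11 to 0.40 for log2 Firmicutes to Bacteroidetes. For AZ1 with DSS they were 0.163 to 0.313 for Shannon (0.313 without DSS with PBS replicate 5, exact p = 0.0179), -1.45 to 0.110 for Verrucomicrobiae, -0.505 to 0.00588 for Bacilli, -1.07 to 0.470 for Erysipelotrichia, -0.247 to 1.45 for Deltaproteobacteria, -1.06 to 1.12 for Deferribacteres, -0.0370 to 0.0942 for Coriobacteriia, -0.121 to 0.0192 for Gammaproteobacteria, -6.53 to -1.39 for Bacteroidia, 2.84 to 6.003 for Clostridia, -0.852 to -0.0480 for the unidentified Actinobacteria, 1.27 to 6.17 for the Firmicutes sum, -0.586 to -0.103 for the facultative sum, 0.14 to 0.52 for log2 Firmicutes to Bacteroidetes, -0.309 to 1.36 for the Proteobacteria sum and -0.830 to 0.0207 for the Actinobacteria sum. For DSS under PBS they were 0.0917 to 0.241 for Shannon, -6.41 to -1.24 for Bacteroidia, 1.03 to 2.61 for Erysipelotrichia, 0.270 to 2.13 for Deferribacteres, 2.70 to 7.60 for the Firmicutes sum, 0.17 to 0.57 for log2 Firmicutes to Bacteroidetes, -3.04 to 0.0954 for Verrucomicrobiae, -0.0775 to 0.00286 for Coriobacteriia and -0.0502 to 0.110 for Gammaproteobacteria. For DSS under AZ1 the count ran from 3 (without AZ1 replicate 3 or 5) to 6 (without DSS with AZ1 replicate 1, where Coriobacteriia were called and Erysipelotrichia were not), Verrucomicrobiae from -3.39 to 0.888, Bacteroidia from -13.02 to -3.80, Gammaproteobacteria from 0.01002 to 0.0510, the Firmicutes sum from 3.12 to 8.80 and log2 Firmicutes to Bacteroidetes from 0.29 to 0.80. The interaction ran from 0.147 to 0.330 for Shannon (0.330 without DSS with PBS replicate 5, permutation p = 0.0317), 0 to 1 in the count (1 without PBS replicate 5, AZ1 replicate 2 or DSS with PBS replicate 4), -8.84 to 0.381 for Bacteroidia, 1.39 to 5.14 for Bacilli, 2.42 to 5.58 for Clostridia, 1.10 to 2.46 for the unidentified Actinobacteria, 0.457 to 2.151 for Deltaproteobacteria, -2.06 to 2.22 for Verrucomicrobiae, -0.298 to 1.88 for Deferribacteres and -0.0749 to 0.0851 for Gammaproteobacteria. Depth is unknown, and what it limits was not assessed here.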

Other observations

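The tests in this part were all chosen after the results above were seen. Taking both arms together, with labels exchanged only within PBS and within AZ1 (31752 exchanges), 4 classes passed for DSS against no DSS, and 5 had an unadjusted p under 0.05. Clostridia rose by 17.6 percentage points (exact p = 3.15e-05, the smallest these exchanges can give, adjusted 0.000346) and Deltaproteobacteria by 3.88 (exact p adjusted to 0.000462). Bacilli fell by 10.6 points (exact p adjusted to 0.000462) and the unidentified Actinobacteria fell by 3.34 points (exact p adjusted to 0.00104). The unidentified Deferribacteres differed by 1.77 points (exact p = 0.0408, adjusted 0.0748). The remainder outside the 10 classes rose by 0.136 points (exact p adjusted to 0.0103), and the Shannon index rose by 0.304 (exact p = 0.000787). These exchanges take the mice as unpaired, although the data hint at a pairing of same-numbered mice under AZ1, which the labels do not state. With same-numbered mice taken as pairs, the Shannon difference under AZ1 alone had an exact p of 0.0625, the smallest 5 pairs can give. Separate housing, sampling or sequencing cannot be told apart from DSS here either.

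For AZ1 against PBS, with labels exchanged within the mice with and without DSS, the exact permutation test called 0 classes, and 1 had an unadjusted p under 0.05. That class was Erysipelotrichia, with a difference of 3.02 points (exact p = 0.0311, adjusted 0.324). The Shannon difference was 0.10 (exact p = 0.242).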
